A study of Homo sapiens with 9 samples.

How the data were processed

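RNA of PANC-1 cells exposed to BRD7552 for 6 h or 72 h, or to DMSO, was labelled with biotin and hybridised to Affymetrix expression arrays with 54675 probe sets, 1 array per sample and 3 per group. The authors deposited 1 table of probe set intensity on a linear scale, with values from 4.54 to 25052. Per the submitters' processing notes MAS5 was used; the version, the scaling target and any later step are not given in the sources used here. Exactly equal values on 2 or more arrays occurred for 59.2% of probe sets, and no value lay below 4.54. Such ties are usual for a summary computed over several arrays and unusual for MAS5, so the summary behind the deposited intensity stays uncertain. Fold changes of dim genes can be understated by it, and ties can make the spread of a gene within a group too small. For DDIT4 and VEGFA, for example, the SD at 6 h was 0 log2 units. No pair of arrays shared more than 5.98% of values, so none was a copy of another. The labels gave group and replicate number of each array, and no batch. The DMSO arrays carry no exposure time.

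Gene names came from the platform's probe table: 41097 probe sets had 1 symbol, 1801 several and 11777 none, and 41043 matched a current gene record by identifier. Probe sets with several symbols and 62 control probe sets were left out. Values were used as deposited, without another normalization or pseudocount, and log2 transformed. Each of 19775 genes was represented by its probe set with the highest mean, and genes with a mean below the median probe set (log2 4.15, linear 17.8) were left out, which kept 12678. For named genes called in a comparison, other probe sets above the filter were set beside the one used. Their sign differed in 2 of 33 cases at 6 h, 10 of 87 at 72 h and 11 of 77 between the times, with 1 pair called in opposite directions. Named genes not called in a comparison are not in these counts. Other probe sets were fitted and adjusted over all 54675 probe sets. Linear models (lmFit and eBayes with a mean-variance trend) were fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, which leaves 6 residual degrees of freedom, for 6 h against DMSO, 72 h against DMSO and 72 h against 6 h. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. "Rose" and "fell" refer to called genes, and errors are standard errors of the limma estimate unless given as SD. PDX1, INS and NKX6-1 were also compared by two-sided exact permutation tests of the group means.

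Gene lists were fixed before the data were examined, as were the test, the grouping and the rule for naming genes. The lists were endocrine transcription factors, islet hormones and secretory machinery, acinar, ductal, leukocyte, endothelial, stromal fibroblast, and red cell and hepatocyte markers, foregut and hepatic endoderm factors, G2/M genes, G1/S and DNA replication genes, p53 targets, ATF4 and amino acid response genes, endoplasmic reticulum chaperones and unfolded protein response, cholesterol synthesis and uptake, fatty acid synthesis, NRF2 and oxidative stress genes, aryl hydrocarbon receptor and xenobiotic genes, heat shock genes, immediate early and ERK targets, NF-kB and inflammatory genes, interferon-stimulated genes, mesenchymal and epithelial genes, TGF-beta and YAP targets, Wnt, Notch and Hedgehog targets, hypoxia genes, chromatin modifiers, histone genes with polyadenylated transcripts, metallothioneins and zinc response, autophagy and lysosome genes, oxidative phosphorylation, ribosomal proteins and reference genes. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists of a comparison. Camera compares a list with the other genes, while fry tests whether the genes of a list change at all. Lists of HOX genes, other homeobox genes, aminoacyl-tRNA synthetases and BMP and ID family genes were added after the data had been seen. The named genes were PDX1, INS, NEUROD1, MAFA and NKX6-1 whatever their p, of which NEUROD1 and MAFA were not analysed here, then the 10 largest rises and falls against DMSO and the 5 between the times among called genes whose arrays did not overlap, and up to 4 called members of each list with the largest change per comparison. Symbols of uncharacterised loci were passed over in the rankings, and genes named outside the rule are marked as such.

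The tests were checked on simulated data with known answers, 200 changed among 12678 genes with the spread of the real groups. For changes of 0.25, 0.5 and 1 log2 units, 16.4%, 53.7% and 89.4% were called in the simulated 6 h comparison with 0 false of 106 calls by limma. In the simulated 72 h comparison 23.9%, 56.7% and 92.4% were called with 7 false of 122 calls. In the simulated comparison of 72 h with 6 h 16.4%, 68.7% and 93.9% were called with 21 false of 140 calls. The shares of false calls in both simulated comparisons with 72 h arrays lay above 5%, most so between the times; the simulated 72 h arrays varied more than the others, and the model shares 1 spread among the groups. In a simulated list test, camera at the preset correlation found 20 genes shifted by 0.25 and did not call 20 unchanged ones. Genes were drawn independently there, so that test does not cover lists whose members vary together. Alternatives were quantile normalization, median centring, a pseudocount of the 20th percentile (8.68), no or a stricter filter on low values, the mean of a gene's probe sets, every probe set on its own, leaving out probe sets with the suffixes _s_at and _x_at, no or a robust trend, the replicate number as a block, only the 6 arrays compared, and leaving out each array in turn. Cyclic loess normalization and array weights were added after the data had been seen. Calculations ran in R 4.3.3 and Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9).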

Results

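Gene expression was measured on 9 Affymetrix arrays of PANC-1, an established human cell line from a pancreatic carcinoma with ductal features. Cells were exposed to the small molecule BRD7552 at 5 uM for 6 h (3 arrays) or 72 h (3 arrays), or to its solvent DMSO (3 arrays, for which the labels give no exposure time). The stated reason for the dose was that it was the lowest giving the strongest induction of PDX1, the homeobox factor required for pancreas formation and for insulin gene activity in beta cells. The comparisons asked which transcripts differed from solvent after short and after long exposure, and which differed between these times. The median probe set signal ran from 16.2 to 18.8 per array on a linear scale. The upper quartile was 97.5 and 99.7 on 72 h replicates 2 and 3, and 112 to 119 on the other 7 arrays. The number of arrays limits the precision. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples. The same 3 DMSO arrays served both comparisons, and time in culture cannot be separated from exposure. The median standard deviation of a gene within a group was 0.0667 log2 units for DMSO, 0.0750 at 6 h and 0.129 at 72 h.

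No difference of PDX1 from DMSO was detected at either time on these arrays. Its brightest probe set had a mean signal of 20.02 ± 1.20 in DMSO, 18.4 ± 1.22 at 6 h and 20.96 ± 5.35 at 72 h (SD, n = 3 each). The log2 change was -0.13 ± 0.17 (SE) at 6 h and 0.035 ± 0.17 at 72 h, with 95% intervals of 0.707 to 1.19 and 0.791 to 1.33 for the ratio to DMSO. These intervals use 1 spread for all groups, and the 72 h one is too narrow for arrays that ran from 15.5 to 26.1. The limma adjusted p was 1.00 and 0.938 over all genes, and 0.907 and 0.903 adjusted over the list alone. A two-sided exact permutation test gave p = 0.3 at 6 h and p = 0.8 at 72 h, where 3 arrays against 3 cannot go below 0.1. The mean PDX1 signal of 19.6 over the 9 arrays lay just above the filter on low values (17.8). The value of PDX1 at 72 h ran up to 0.24 with 1 array left out, and turned negative when the probe sets of PDX1 were averaged (-0.0082), without DMSO replicate 2 (-0.0099) and without 72 h replicate 3 (-0.14). The other PDX1 probe sets were dimmer, with log2 changes of -0.10 and -0.027 and 0.0077 and -0.032.

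INS, which encodes insulin, had a mean signal of 7.40 over the 9 arrays, below the filter on low values, with log2 changes of -0.052 ± 0.12 at 6 h and -0.14 ± 0.12 at 72 h. NKX6-1, a beta cell homeobox factor, was also dim, at a mean signal of 10.6, and its log2 changes were 0.078 ± 0.12 and 0.15 ± 0.12. Neither was called by limma without the filter at either time (adjusted p = 0.536 for INS and 0.504 for NKX6-1 at 72 h). A two-sided exact permutation test, which cannot go below 0.1 here, gave p = 0.7 and 0.5 for INS and 0.7 and 0.4 for NKX6-1. NEUROD1 and MAFA were not analysed here.

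**Figure D1:**
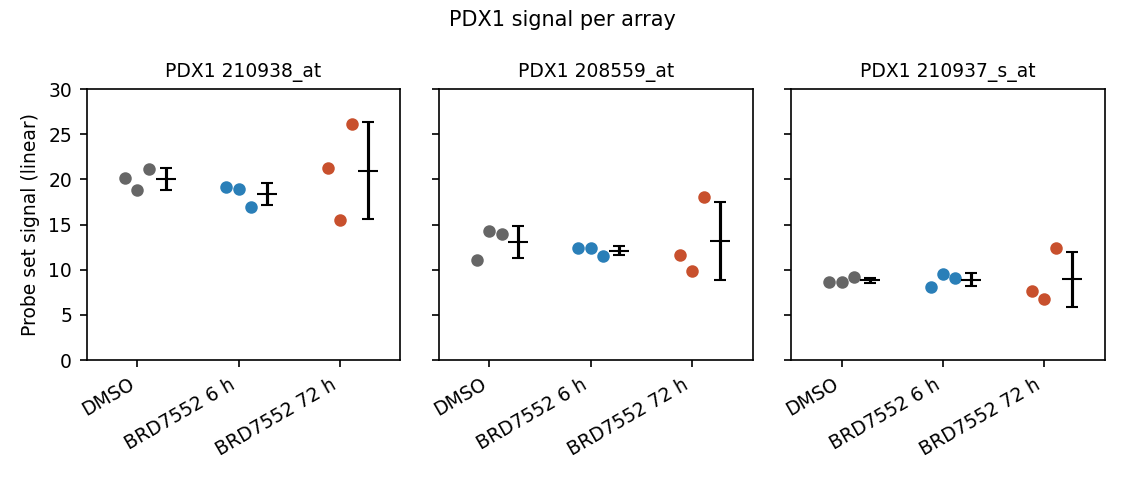
Linear signal of the 3 PDX1 probe sets on each array (points), by group, with the group mean and 1 SD as bars (n = 3 arrays per group). For the brightest probe set the group means were 20.02 in DMSO, 18.4 at 6 h and 20.96 at 72 h, and the 72 h arrays had the widest spread, with an SD of 5.35.

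After 6 h of BRD7552, genes of the ATF4 and amino acid response rose. SESN2, a sestrin that restrains mTORC1, rose 1.96-fold (log2 0.97 ± 0.099, SE, n = 3 arrays per group), and DDIT4, a stress-induced mTORC1 inhibitor, rose 1.82-fold (log2 0.87 ± 0.045). TRIB3, a pseudokinase induced by ATF4, rose 1.70-fold, DDIT3, which encodes the factor CHOP, 1.65-fold, and CHAC1, an enzyme that degrades glutathione, 1.62-fold. ASNS, asparagine synthetase, rose 1.21-fold. The list of ATF4 and amino acid response genes had 20 measured members, of which 8 rose, 12 did not pass and the median log2 change was 0.35. Adjusted over the list alone, 15 members passed, each of them higher. The list as a whole shifted upwards (camera adjusted p = 1.3e-35), also with adjusted p = 0.00112 with an estimated correlation. CHAC1 no longer passed without any 1 of the 3 DMSO arrays.

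Over all 12678 genes, 60 changed at 6 h, of which 46 rose and 14 fell, while 582 had an unadjusted p under 0.05. The DMSO and 6 h arrays did not overlap for any of the 60 called genes, nor for 12.2% of all genes, where chance gives 10%. INSIG1, the sterol-regulated retention protein of the SREBP pathway, had the largest rise at 2.01-fold (log2 1.01 ± 0.12, limma adjusted p = 0.000396). By this probe set it was the 1 gene past 2-fold. Other INSIG1 probe sets stood at 0.54, not passing, and 0.84, passing. The other large rises included the antisense transcript RUSC1-AS1 (1.88-fold), the axial patterning factors HOXC9 (1.74-fold) and HOXB8 (1.62-fold), and PAX2, a factor of kidney development (1.65-fold). KISS1R, the kisspeptin receptor, rose 1.45-fold, GDF15, a stress-induced cytokine, 1.53-fold, and ADCY9, an adenylyl cyclase, 1.27-fold. Among the falls, SKIL, a repressor of SMAD signalling that TGF-beta itself induces, fell by 0.51 on the log2 scale (SE 0.093) and EDN1, which encodes endothelin 1, by 0.47 (SE 0.061). HES1, a Notch target repressor, fell by 0.43 on the log2 scale, ID2, an inhibitor of basic helix-loop-helix factors, fell by 0.42, and RNF145, a membrane ubiquitin ligase, fell by 0.40. Smaller falls were those of the homeobox gene DLX2 (-0.33), TIPARP, a target of the aryl hydrocarbon receptor (-0.27), UGCG, which makes glucosylceramide (-0.26), ID3 (-0.26) and the RNA-binding protein gene TARDBP (-0.25). With each array centred on its median, HES1, DLX2, TIPARP, UGCG, ID3 and TARDBP no longer passed, and the count over all genes was 37. It was 31, 38 and 34 without DMSO replicates 1, 2 and 3, and 28 and 34 without 6 h replicates 2 and 3, while INSIG1 stayed under 2-fold without DMSO replicate 1 and without 6 h replicate 2. With array weights, tried after the data had been seen, the number of genes changed at 6 h against DMSO was higher, at 211. The 2 other TARDBP probe sets stood at -0.15 and 0.018, of which none passed.

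Sterol synthesis genes rose at 6 h. Besides INSIG1, IDI1, an isomerase of isoprenoid synthesis, rose 1.42-fold (log2 0.51 ± 0.053) and MSMO1, a methylsterol oxidase, 1.41-fold (log2 0.49 ± 0.056). The 17 measured genes of cholesterol synthesis and uptake held 3 that rose and 14 that did not pass, and 9 passed adjusted over the list alone. Their median log2 change was 0.17 (camera adjusted p = 3.4e-14, and adjusted p = 0.0132 with an estimated correlation). In the fatty acid synthesis list, SCD, stearoyl-CoA desaturase, rose 1.16-fold and 10 of 11 members did not pass, with 2 adjusted over the list alone. That list's shift (camera adjusted p = 7.6e-05) had adjusted p = 0.0979 with an estimated correlation. HERPUD1, which acts in degradation from the endoplasmic reticulum, rose 1.33-fold, and the other 18 measured members of the endoplasmic reticulum chaperone and unfolded protein response list did not pass. Adjusted over the list alone, 2 of the 19 passed, HERPUD1 as higher and 1 as lower, and the camera adjusted p of 0.000733 became adjusted p = 0.167 with an estimated correlation.

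Genes downstream of TGF-beta family signals fell at 6 h. SKIL fell by 0.51 on the log2 scale, and the inhibitors of differentiation ID1, ID2 and ID3 fell by 0.23, 0.42 and 0.26 (SE 0.043, 0.072 and 0.048). These were the 4 that passed of 18 measured TGF-beta and YAP target genes, where 14 did not pass and 5 fell adjusted over the list alone. The median log2 change was -0.13 (camera adjusted p = 1.2e-09, and adjusted p = 0.0252 with an estimated correlation). CCN2, a matrix protein gene induced by TGF-beta and YAP, stood at -0.16. Centring each array on its median left 2 of the 4 calls in this list.

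Several other lists shifted at 6 h by camera with its preset correlation and not with an estimated one. In the foregut and hepatic endoderm list, GATA4, an endoderm factor, rose 1.42-fold and 7 of 8 members did not pass, with 2 adjusted over the list alone (camera adjusted p = 0.00376, and adjusted p = 0.257 with an estimated correlation). The 3 other GATA4 probe sets stood at 0.063, 0.028 and -0.29, of which none passed. JUN, a component of AP-1, fell by 0.18 on the log2 scale, as the 1 of 17 immediate early and ERK target genes that passed, with 3 adjusted over the list alone (1.8e-05, and adjusted p = 0.0979 with an estimated correlation). The chemokine gene CCL2 fell by 0.23, as the 1 of 12 NF-kB and inflammatory genes, with 1 adjusted over the list alone (0.00104, and adjusted p = 0.141 with an estimated correlation). VEGFA, the angiogenic growth factor, rose 1.33-fold, as the 1 of 19 hypoxia genes, with 1 adjusted over the list alone (0.0101, and adjusted p = 0.311 with an estimated correlation). In the metallothionein and zinc response list of 8, limma called 0 over all genes, 6 had an unadjusted p under 0.05 and 4 were lower adjusted over the list alone (7.6e-05, and adjusted p = 0.220 with an estimated correlation). For 14 NRF2 and oxidative stress genes, 13 epithelial genes and 25 G2/M genes, limma called 0 in each list. At an unadjusted p under 0.05 they held 1, 2 and 4 genes, and adjusted over the list alone 1, 1 and 0. Their camera adjusted p values were 0.0101, 0.0477 and 0.00220, against adjusted p = 0.133, 0.167 and 0.318 with an estimated correlation. The epithelial call ended under each other scaling and without DMSO replicates 2 and 3 or any 1 of the 6 h arrays, the hypoxia call without 6 h replicate 3 and the G2/M call without DMSO replicate 2.

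The remaining lists did not shift at 6 h by camera, and directional fry passed for 0 of them. SESN2 and GDF15 were the 2 of 19 p53 target genes that rose, with 3 adjusted over the list alone (camera adjusted p = 0.225). NRARP, a Notch target, rose 1.43-fold while HES1 fell, among 13 Wnt, Notch and Hedgehog target genes with 4 adjusted over the list alone (camera adjusted p = 0.830), whose median of -0.077 and mean of 0.0072 differed in sign. HES1 was also the 1 of 12 ductal markers that fell, with 1 adjusted over the list alone (0.278), and TIPARP the 1 of 9 aryl hydrocarbon receptor and xenobiotic genes, with 1 (0.379). MAP1LC3B, an autophagosome protein gene, rose 1.19-fold as the 1 of 17 autophagy and lysosome genes, with 1 adjusted over the list alone (0.230). Limma called 0 genes at 6 h in the lists of G1/S and DNA replication genes, interferon-stimulated genes, heat shock genes, mesenchymal genes, chromatin modifiers, histone genes, oxidative phosphorylation, ribosomal proteins, reference genes, endocrine transcription factors and islet genes. At an unadjusted p under 0.05 these held 2, 1, 0, 1, 0, 0, 0, 0, 0, 0 and 0 genes in that order. Adjusted over the list alone, 1 interferon-stimulated gene was higher and the other lists of that group held 0. Their camera adjusted p values ran from 0.205 (interferon-stimulated genes) to 0.913 (endocrine transcription factors). The endocrine list had a negative median of -0.028 against an upward camera direction, and the mesenchymal list a median of -0.0049 against a mean of 0.00074, a median that changed sign with median centring, as did the ribosomal median of -0.00084 (also with cyclic loess).

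**Figure D2:**
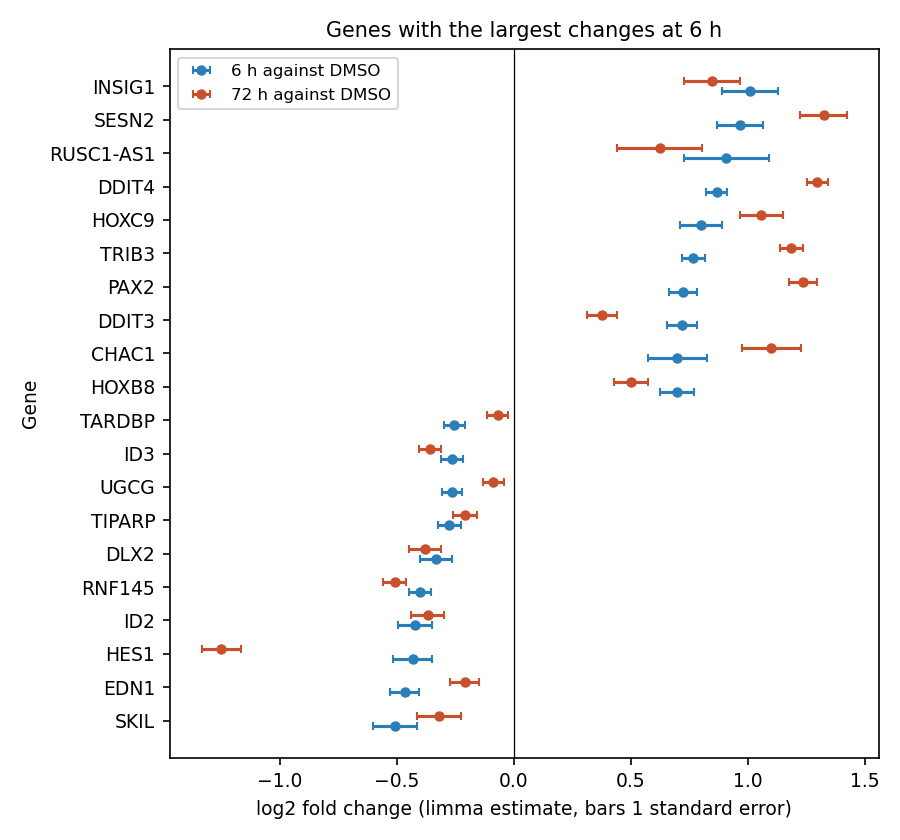
Log2 fold change (limma estimate, bars 1 standard error, n = 3 arrays per group) of the 10 genes with the largest rise and the 10 with the largest fall at 6 h, at 6 h (blue) and at 72 h (red) against DMSO. INSIG1 stood at 1.01 at 6 h and 0.85 at 72 h, and HES1 at -0.43 and -1.25.

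After 72 h the largest fall was that of PODXL, and KISS1R had the largest rise. PODXL, the sialomucin podocalyxin, fell by 2.62 on the log2 scale (SE 0.070, n = 3 arrays per group), TFPI2, a protease inhibitor of the extracellular matrix, by 2.54 (SE 0.19), and GAL, the neuropeptide galanin, by 2.26 (SE 0.080). TGM2, a transglutaminase, stood at -2.01, the kinase gene SGK1 at -2.01, MATN2, a matrix filament protein, at -1.97, the adhesion molecule gene CLMP at -1.85, FAXC at -1.82, the metalloprotease gene ADAM19 at -1.79 and the interferon-induced IFIT3 at -1.78, each passing the test. The other ADAM19 probe set stood at 0.27 and did not pass. KISS1R rose 3.95-fold (log2 1.98 ± 0.10), RAB26, a small GTPase of secretory vesicles, 2.93-fold (log2 1.55 ± 0.11) and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, 2.86-fold (log2 1.52 ± 0.084). IFITM1, an interferon-induced membrane protein gene, rose 2.85-fold, CEBPA, a factor of hepatocyte and adipocyte differentiation, 2.74-fold, TM7SF2, a sterol reductase, 2.64-fold and FRAT1, a GSK3-binding protein gene, 2.55-fold. SESN2, ADCY9 and SLC7A11, the cystine importer, completed the largest rises at 2.51-fold, 2.49-fold and 2.49-fold.

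In all, 3378 of 12678 genes changed at 72 h, 1056 of them higher and 2322 lower (68.7% lower), and 104 changed at least 2-fold (32 higher, 72 lower). The split of the genes changed at 72 h against DMSO depended on the scaling: falls made up 54.3% after quantile normalization (1659 higher, 1973 lower), 52.5% after cyclic loess (1727 and 1911) and 60.7% with arrays centred on their medians (820 and 1266). The DMSO and 72 h arrays did not overlap for 3261 of the called genes and for 36.9% of all genes, where chance gives 10%. The 72 h arrays were less alike than the others, with a mean Spearman correlation within the group of 0.958 to 0.971, against 0.985 to 0.990 for DMSO and 6 h arrays. Their ratio of 3' to 5' ACTB control signal was 2.07 to 2.21, against 1.74 to 2.05, and the GAPDH ratio 1.34 to 1.39, against 1.27 to 1.35. These differences between array groups apply to every 72 h list described here. Of the named genes called at 72 h that have further probe sets above the filter, 23 of 56 had none of these called. Among them were ADCY9 (another probe set at 0.32), PLK3 (-0.075 and -0.014), GINS2 (-0.024) and LSS (0.0022), chosen for the gap after the values were seen. At 6 h this held for 16 of 19 such genes, and between the times for 26 of 48. The other probe sets were adjusted over all probe sets and the genes over the filtered genes only. These calls are therefore not on equal terms, and the shares are no clean measure of missing support. For ID2 at 6 h the other probe set stood at -0.43 without passing, and the one used at -0.42 passed. By camera, only the ATF4 list kept its call at 72 h with an estimated correlation, among the lists fixed beforehand.

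**Figure D3:**
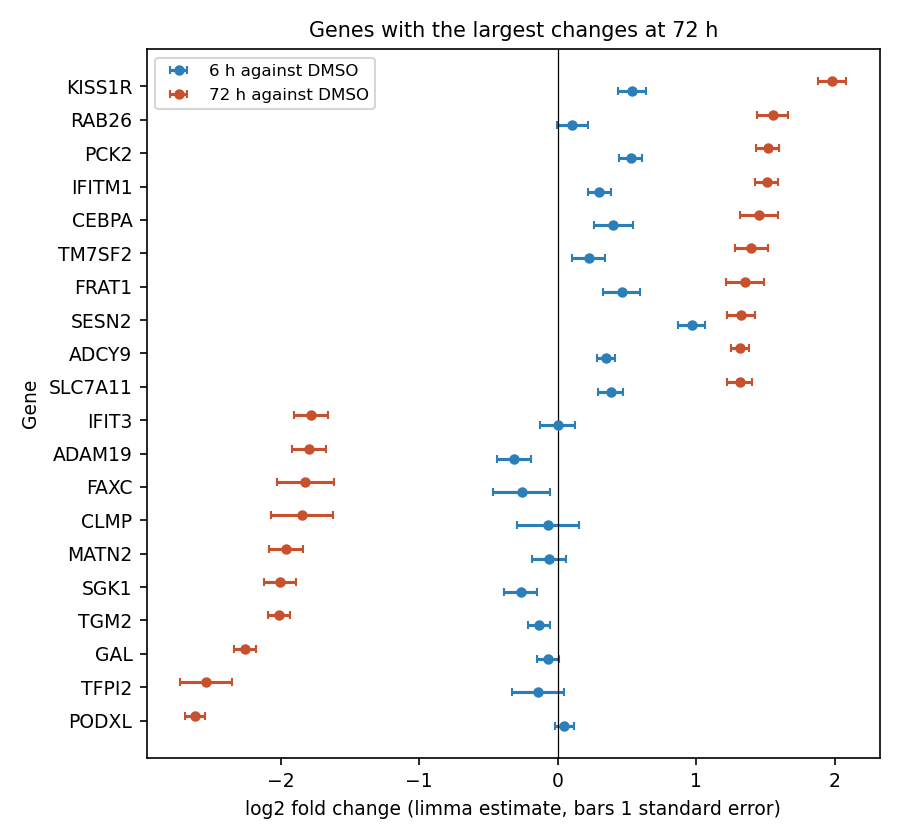
Log2 fold change (limma estimate, bars 1 standard error, n = 3 arrays per group) of the 10 genes with the largest rise and the 10 with the largest fall at 72 h, at 6 h (blue) and at 72 h (red) against DMSO. KISS1R stood at 0.54 at 6 h and 1.98 at 72 h, and PODXL at 0.049 and -2.62.

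Most genes of the amino acid response and part of the oxidative stress genes rose at 72 h. Of 20 ATF4 and amino acid response genes, 18 rose, 1 fell and 1 did not pass, with 19 adjusted over the list alone and a median log2 change of 0.55. SESN2, SLC7A11, DDIT4 and ASNS rose 2.51-fold, 2.49-fold, 2.46-fold and 2.42-fold (SE 0.099, 0.089, 0.045 and 0.039 log2 units). The exception was ATF5, a relative of ATF4, which fell by 0.25 on the log2 scale and was singled out after its value was seen. The shift of the list had a camera adjusted p of 9.4e-20, and adjusted p = 0.00604 with an estimated correlation. Of 14 NRF2 and oxidative stress genes, 7 rose and 7 did not pass, with 7 adjusted over the list alone and a median of 0.13. SLC7A11 belongs to this list too. TXNRD1, thioredoxin reductase, rose 1.30-fold, the NRF2 target PIR 1.29-fold and the quinone reductase gene NQO1 1.25-fold. For these genes the camera adjusted p of 0.000140 became adjusted p = 0.0750 with an estimated correlation.

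Genes of DNA replication fell at 72 h. Of 25 G1/S and DNA replication genes, 19 fell and 6 did not pass, with 19 adjusted over the list alone and a median log2 change of -0.27. The replication fork genes GINS2 and CDC45 fell by 0.64 and 0.62 on the log2 scale (SE 0.068 and 0.085). CCNE1, cyclin E1, and the origin licensing gene CDC6 fell by 0.51 and 0.45 (SE 0.057 and 0.062). The camera adjusted p of 6.6e-05 became adjusted p = 0.241 with an estimated correlation, and 9 of these genes fell with median centring. The 25 G2/M genes were divided: 7 rose, 3 fell and 15 did not pass, with 10 adjusted over the list alone. TOP2A, a topoisomerase, rose 1.22-fold and the mitotic kinesin gene KIF11 1.19-fold, while UBE2C and AURKB, which act in mitotic exit and chromosome segregation, fell by 0.39 and 0.27 on the log2 scale. The other TOP2A probe set stood at -0.040 and did not pass. The median of 0.061 gave a camera adjusted p of 0.0403 and adjusted p = 0.495 with an estimated correlation. That call ended under each other scaling and without DMSO replicate 1 or 72 h replicate 2. Of 11 histone genes with polyadenylated transcripts, 6 rose and 5 did not pass, with 8 adjusted over the list alone. The core and linker histone genes H2AC6, H2BC4 and H1-2 rose 1.71-fold, 1.63-fold and 1.55-fold. The histone shift had a camera adjusted p of 0.000122 and adjusted p = 0.183 with an estimated correlation.

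Markers of pancreatic duct cells fell more often than they rose at 72 h, and 4 endoderm factors rose by their brightest probe sets. HES1 fell by 1.25 on the log2 scale (SE 0.082), KRT7, a keratin of ductal epithelium, by 1.07 (SE 0.18), CA2, carbonic anhydrase 2, by 1.000 (SE 0.16) and KRT8 by 0.47 (SE 0.038). The 12 ductal markers comprised 6 that fell, 1 that rose and 5 that did not pass, with 8 adjusted over the list alone. The member that rose was the mucin gene MUC1 (log2 0.36), singled out after its value was seen. The ductal shift had a camera adjusted p of 0.0143 and adjusted p = 0.183 with an estimated correlation. Of 8 foregut and hepatic endoderm factors, CEBPA, GATA6, GATA4 and HHEX rose 2.74-fold, 1.73-fold, 1.68-fold and 1.22-fold, 4 did not pass and 5 passed adjusted over the list alone. Their camera adjusted p of 0.0137 became adjusted p = 0.294 with an estimated correlation. The 3 other GATA4 probe sets stood at -0.12, 0.47 and -0.43, of which none passed. The other HHEX probe set stood at 0.087 and did not pass. CEBPA was dim in DMSO, with a mean log2 signal of 4.33 close to the filter on low values, and stood at 5.78 at 72 h. Of 6 endocrine transcription factors measured, FOXA2, which acts upstream of PDX1 in pancreas development, rose 1.16-fold, 5 did not pass and 1 passed adjusted over the list alone (camera adjusted p = 0.119). FOXA2 turned to -0.013 when its probe sets were averaged. Of 6 genes of islet hormones and secretory machinery, PTPRN2, a dense-core vesicle phosphatase, fell by 0.83 on the log2 scale, 5 did not pass and 1 passed adjusted over the list alone (camera adjusted p = 0.697). The islet median of -0.074 changed sign after cyclic loess.

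Part of the mesenchymal genes and of the TGF-beta and YAP targets fell at 72 h. By their brightest probe sets COL6A1 and COL5A1, collagen chains, fell by 1.45 and 1.01 on the log2 scale (SE 0.12 and 0.19), LOX, which crosslinks collagen, by 0.84 and the calcium-binding S100A4 by 0.57. The 3 other COL6A1 probe sets did not pass (-0.084, -0.10 and -0.49). The 4 genes were among 6 of 14 mesenchymal genes that fell, with 8 not passing and 6 adjusted over the list alone. The camera adjusted p of 0.0342 became adjusted p = 0.241 with an estimated correlation, and the call ended without 72 h replicate 1. Of 18 TGF-beta and YAP target genes, 9 fell and 9 did not pass, with 11 adjusted over the list alone (camera adjusted p = 0.0137, and adjusted p = 0.241 with an estimated correlation). F3, tissue factor, fell by 1.01 on the log2 scale, PMEPA1, a SMAD target, by 0.79, CCN2 by 0.60 and ID2 by 0.37. The 13 epithelial genes went both ways, as 3 rose, 2 fell and 8 did not pass, with 5 adjusted over the list alone (camera adjusted p = 0.130). The junction genes OCLN, JUP and CLDN7 rose 1.53-fold, 1.496-fold and 1.43-fold, and the tight junction gene CLDN4 fell by 0.70 on the log2 scale, where the other CLDN4 probe set stood at 0.10 and did not pass. Among 13 Wnt, Notch and Hedgehog target genes, 2 rose, 4 fell and 7 did not pass, with 6 adjusted over the list alone (camera adjusted p = 0.881). PTCH1, a Hedgehog receptor and target, and NRARP rose 2.34-fold and 1.82-fold, and HES1 and the Notch ligand gene JAG1 fell by 1.25 and 0.76.

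Immediate early genes and NF-kB genes fell more often than they rose at 72 h. Of 17 immediate early and ERK target genes, 1 rose, 9 fell and 7 did not pass, with 10 adjusted over the list alone. SPRY4 and DUSP5, feedback inhibitors of ERK signalling, fell by 0.78 and 0.57 on the log2 scale, and JUN by 0.41. The camera adjusted p was 0.0137, with adjusted p = 0.241 with an estimated correlation, and the call ended without 72 h replicate 1. Of 12 NF-kB and inflammatory genes, 1 rose, 7 fell and 4 did not pass, with 8 adjusted over the list alone (camera adjusted p = 0.271). The chemokine genes CXCL8, CXCL1 and CCL2 fell by 1.37, 0.81 and 0.57, and the cytokine gene LIF by 0.61. After quantile normalization 3 of these genes rose and 5 fell. Interferon-stimulated genes split: of 14, 3 rose, 7 fell and 4 did not pass, with 12 adjusted over the list alone (camera adjusted p = 0.603). IFIT3, IFIT2 and OASL, antiviral effectors, fell by 1.78, 1.36 and 1.01, while IFITM1 rose 2.85-fold. The fry test for a shared direction passed for 17 of 29 lists at 72 h, of which 5 had no camera call: NF-kB (adjusted p = 0.00188), reticulum chaperone (0.00798), epithelial (0.00798), autophagy (0.00798) and reference genes (0.00236). For the interferon list it gave 0.222. Its form for changes in either direction passed for 27 of 29 lists at 72 h, so it sets no list apart. Fry tests against 0, while the median over all genes at 72 h was -0.062, near the medians of the reticulum chaperone (-0.061) and reference lists (-0.066).

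Metallothioneins and part of the chaperone genes fell at 72 h. All 8 measured metallothionein and zinc response genes fell, with 8 adjusted over the list alone. MT1X and MT1G, zinc-binding metallothioneins, fell by 0.35 and 0.35 on the log2 scale. MT1X, MT1G and MT1H were read by probe sets with the suffix _x_at, which marks probes that can be shared between genes. Signal shared between metallothioneins was not tested, so the members of this list may not be separate readings in any comparison. With camera the adjusted p of 0.00118 became adjusted p = 0.278 with an estimated correlation, and 4 fell with median centring. Heat shock genes fell in 6 of 13 cases and 7 did not pass, with 8 adjusted over the list alone. The chaperone genes DNAJB1 and HSPB1 fell by 0.39 and 0.30. Their camera adjusted p was 0.0161, with adjusted p = 0.241 with an estimated correlation, and the call ended with median centring and without 72 h replicate 1. Of 19 endoplasmic reticulum chaperone and unfolded protein response genes, 3 rose, 6 fell and 10 did not pass, with 9 adjusted over the list alone (camera adjusted p = 0.561). MANF, a secreted reticulum stress protein, and the co-chaperone DNAJB11 fell by 0.71 and 0.36, and HERPUD1 rose 1.28-fold. Among 19 hypoxia genes, 3 rose, 6 fell and 10 did not pass, with 11 adjusted over the list alone (camera adjusted p = 0.603). Of these, ENO2, PDK1 and PFKFB3 fell by 0.71, 0.64 and 0.51, and VEGFA rose 1.504-fold. The 3 other VEGFA probe sets stood at 0.12, -0.081 and 0.18, of which none passed. Among 19 p53 target genes, 4 rose, 7 fell and 8 did not pass, with 11 adjusted over the list alone (camera adjusted p = 0.961). SESN2 and GDF15 rose 2.51-fold and 2.02-fold, and the kinase gene PLK3 and the cell cycle inhibitor CDKN1A fell by 0.89 and 0.64.

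Lipid and xenobiotic genes changed in part at 72 h. Of 17 cholesterol genes, 5 rose, 3 fell and 9 did not pass, with 11 adjusted over the list alone (camera adjusted p = 0.130). INSIG1, IDI1 and the cyclase gene LSS rose 1.80-fold, 1.35-fold and 1.31-fold, and HSD17B7, a sterol ketoreductase, fell by 0.41 on the log2 scale. Other INSIG1 probe sets stood at 0.19, not passing, and 0.42, passing. The 2 other IDI1 probe sets stood at 0.46 and -0.22, of which 1 passed, the higher one. SREBF1, the master factor of fatty acid synthesis, rose 2.21-fold, and the other 10 measured genes of that list did not pass, with 1 adjusted over the list alone (camera adjusted p = 0.493). Another SREBF1 probe set stood at 0.45 and did not pass. For SCD, which did not pass by its brightest probe set, the 3 others passed as lower (-1.02, -0.89 and -0.87), so the size of its change at 72 h, and whether it passes, depend on the probe set. Of 9 aryl hydrocarbon receptor and xenobiotic genes, 3 rose, 1 fell and 5 did not pass, with 4 adjusted over the list alone. CYP1B1, a target of that receptor, rose 1.42-fold and TIPARP, another, fell by 0.21 on the log2 scale. The 3 other CYP1B1 probe sets stood at -0.28, 0.62 and 0.58, of which 2 passed, both higher. The shift had a camera adjusted p of 0.00308 and adjusted p = 0.231 with an estimated correlation.

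Housekeeping, autophagy and chromatin lists held called genes at 72 h as well. Over all genes 3378 of 12678 were called (1056 higher and 2322 lower), so a few calls do not set a list apart. Of 21 oxidative phosphorylation genes, 6 rose, 2 fell and 13 did not pass, with 9 adjusted over the list alone. NDUFB3, a complex I subunit, rose 1.22-fold. The camera adjusted p of 0.0342 became adjusted p = 0.349 with an estimated correlation, and the call ended after quantile and cyclic loess normalization and without 72 h replicate 2. Of 13 ribosomal protein genes, RPL18 fell by 0.13 on the log2 scale and 12 did not pass, with 1 adjusted over the list alone (camera adjusted p = 0.868). The 2 other RPL18 probe sets stood at -0.054 and 0.12, of which none passed. The ribosomal median of -0.015 lay against an upward camera direction and changed sign with median centring. Of 17 autophagy and lysosome genes, 2 rose, 4 fell and 11 did not pass, with 7 adjusted over the list alone (camera adjusted p = 0.731). The lysosomal protease genes CTSL and CTSB fell by 0.85 and 0.48, and MAP1LC3B rose 1.44-fold. Of 33 chromatin modifiers, 5 fell, 4 of them adjusted over the list alone, among them the deacetylase gene HDAC4 (-0.45), and 28 did not pass (camera adjusted p = 0.918). The medians of the autophagy list (-0.016) and the chromatin list (-0.029, against an upward camera direction) changed sign under each of the 3 other scalings. Reference genes in common use also fell in part: HPRT1, TBP, GUSB and SDHA fell by 0.26, 0.23, 0.18 and 0.16, 6 of 10 did not pass and 4 passed adjusted over the list alone (camera adjusted p = 0.493). With quantile normalization 2 of them fell, with cyclic loess 3, and with median centring limma called 0, against 5 at an unadjusted p under 0.05 without it.

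Markers of other cell types were too few above the filter to test as lists. Limma called 0 of the 3 acinar, 3 leukocyte, 4 endothelial, 4 stromal fibroblast and 3 red cell and hepatocyte markers measured, at either time and adjusted over the list alone. At an unadjusted p under 0.05, 1 leukocyte and 1 stromal marker passed at 72 h and 0 at 6 h. Their medians at 6 h and 72 h were 0.072 and -0.18 (acinar), 0.029 and -0.20 (leukocyte), -0.050 and 0.062 (endothelial), 0.016 and -0.028 (stromal) and 0.069 and -0.083 (red cell and hepatocyte). The stromal median at 72 h changed sign under each other scaling, and the red cell and hepatocyte median after quantile and cyclic loess normalization.

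**Figure D4:**
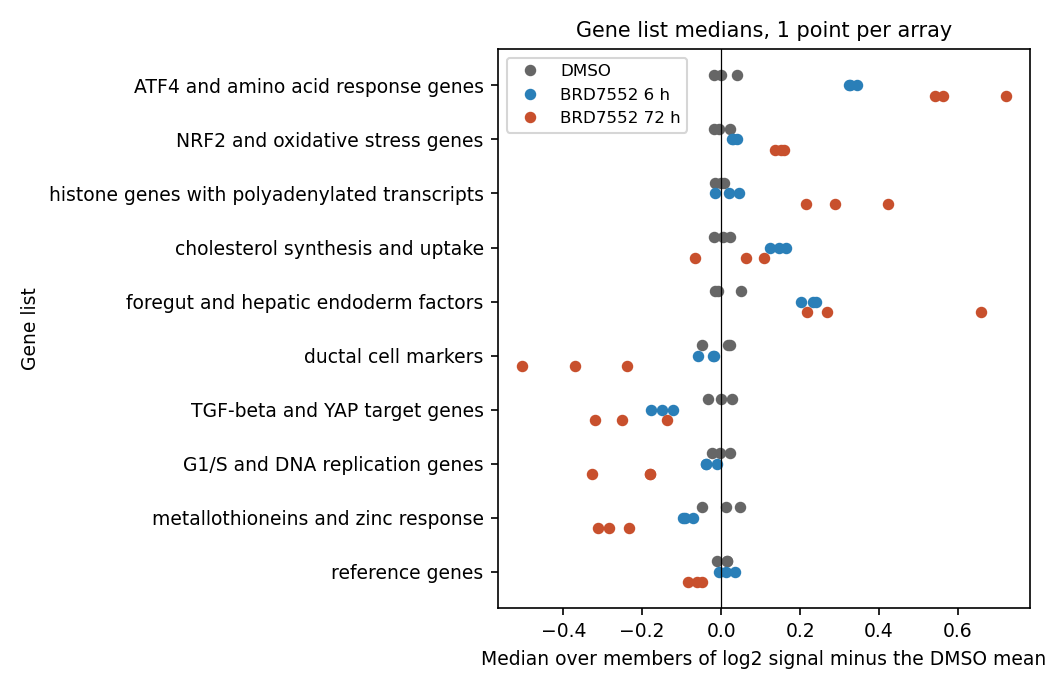
Median over the measured members of 10 gene lists of log2 signal minus the DMSO mean, 1 point per array (DMSO grey, 6 h blue, 72 h red). The ATF4 list stood at 0.32 to 0.34 on the 6 h arrays and 0.54 to 0.72 on the 72 h arrays, and the reference genes at -0.084 to -0.049 on the 72 h arrays.

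Between 6 h and 72 h of BRD7552, 3037 genes differed, 923 higher and 2114 lower at 72 h (69.6% lower), and 65 at least 2-fold. Among the genes different between 72 h and 6 h the lower share was 53.2% after quantile normalization, 51.8% after cyclic loess and 65.8% with median centring. KISS1R and RAB26 were 2.73-fold and 2.72-fold higher at 72 h (SE 0.10 and 0.11 log2 units), CCM2L, a relative of a vascular scaffold gene, 2.54-fold (another probe set at 0.059, not passing), IFITM1 2.31-fold and TM7SF2 2.26-fold. PODXL stood at -2.67 against 6 h, TFPI2 at -2.40, GAL at -2.19, MATN2 at -1.90 and TGM2 at -1.88, each passing. The arrays of the compared groups did not overlap for 2903 of the called genes and for 33.7% of all genes. The ATF4 list rose further, as 12 of 20 members were higher at 72 h, 1 lower and 7 did not pass, with 13 adjusted over the list alone (camera adjusted p = 7.6e-08, and adjusted p = 0.0704 with an estimated correlation). The member that was lower was DDIT3 (-0.34). EDN1 was higher at 72 h than at 6 h (0.26). The 2 other EDN1 probe sets stood at -0.43 and 0.091, of which 1 passed, as lower.

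With the preset correlation, camera also placed several lists apart between the times, and none of these calls held with an estimated correlation. Lower at 72 h were 17 of 25 G1/S and DNA replication genes, with 17 adjusted over the list alone (adjusted p = 0.000119, and 0.272 with an estimated correlation). CDC45 stood at -0.56 and GINS2 at -0.53, where the other GINS2 probe set stood at 0.040 and did not pass. Histone genes were higher for 7 of 11, with 7 adjusted over the list alone (adjusted p = 9.6e-05, and 0.137 with an estimated correlation), among them H1-2 (1.63-fold). In the G2/M list 8 higher and 3 lower genes passed, with 14 adjusted over the list alone (adjusted p = 0.00125, and 0.336 with an estimated correlation), KIF11 being 1.27-fold higher. NRF2 genes passed as 7 higher and 1 lower, with 8 adjusted over the list alone (adjusted p = 0.00183, and 0.137 with an estimated correlation), PIR being 1.28-fold higher. For the aryl hydrocarbon receptor list 2 were higher, with 3 adjusted over the list alone (adjusted p = 0.000226, and 0.137 with an estimated correlation), CYP1B1 being 1.43-fold higher. Heat shock genes were lower for 8 of 13, with 10 adjusted over the list alone (adjusted p = 0.00743, and 0.270 with an estimated correlation), DNAJB1 standing at -0.46. Ductal markers passed as 1 higher and 5 lower, with 9 adjusted over the list alone (adjusted p = 0.0177, and 0.153 with an estimated correlation), KRT7 standing at -1.004. Metallothioneins were lower for 5 of 8, with 5 adjusted over the list alone (adjusted p = 0.0304, and 0.456 with an estimated correlation). Mesenchymal genes were lower for 7 of 14, with 7 adjusted over the list alone (adjusted p = 0.0414, and 0.277 with an estimated correlation), COL6A1 standing at -1.45 and its 3 other probe sets, none passing, at -0.080, 0.11 and -0.37. Reticulum chaperones were lower for 6 of 19, with 9 adjusted over the list alone (adjusted p = 0.0480, and 0.384 with an estimated correlation), MANF standing at -0.91. Oxidative phosphorylation genes passed as 7 higher and 1 lower, with 10 adjusted over the list alone (adjusted p = 0.0148, and 0.336 with an estimated correlation). The ductal, heat shock, mesenchymal, metallothionein and reticulum calls ended without 72 h replicate 1.

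The other 17 lists tested were not set apart from the remaining genes by camera between the times. The fry test, which asks for a shared direction without that comparison, passed for 8 of them, each lower at 72 h by its median: cholesterol (adjusted p = 0.00269), reference (0.00184), autophagy (0.00345), immediate early (0.00507), hypoxia (0.00507), NF-kB (0.0219), TGF-beta and YAP (0.0273) and Wnt, Notch and Hedgehog (0.0455) genes. Fry tests against 0, and the median over all genes was -0.060 as deposited and 0.0043 after quantile normalization. The reference (-0.068), TGF-beta and YAP (-0.070) and autophagy (-0.080) medians lay near the former, so these fry calls are not set apart from it. Genes higher and lower at 72 h, with the number that passed adjusted over the list alone in parentheses, were 1 and 6 of 17 cholesterol genes (7), 1 and 1 of 11 fatty acid synthesis genes (2), 0 and 6 of 17 immediate early genes (6) and 0 and 5 of 12 NF-kB genes (5). The same counts were 3 and 7 of 14 interferon-stimulated genes (11), 4 and 2 of 13 epithelial genes (6), 1 and 3 of 18 TGF-beta and YAP targets (4), 2 and 3 of 13 Wnt, Notch and Hedgehog targets (7) and 2 and 6 of 19 hypoxia genes (8). They were 5 and 7 of 19 p53 targets (14), 0 and 5 of 33 chromatin modifiers (3), 2 and 4 of 17 autophagy and lysosome genes (7), 1 and 2 of 10 reference genes (4) and 1 and 0 of 8 foregut and hepatic endoderm factors (1). Camera adjusted p values of these lists ran from 0.0588 (foregut and hepatic endoderm factors) to 0.889 (Wnt, Notch and Hedgehog targets). MSMO1 and HSD17B7 stood at -0.16 and -0.66 against 6 h, SREBF1 was 1.60-fold and SCD -0.28 log2 units from its 6 h level (other SCD probe sets -1.12, -1.14 and -1.04), and CXCL8 stood at -0.89. PTPRN2 was the 1 of 6 islet genes that differed (-0.73, 1 adjusted over the list alone, camera adjusted p = 0.710). Limma called 0 of 6 endocrine factors and 0 of 13 ribosomal genes, with 0 and 1 at an unadjusted p under 0.05, 0 in each adjusted over the list alone, and adjusted p values of 0.0986 and 0.648. The medians of the Wnt, chromatin, autophagy, ribosomal and islet lists changed sign under 1 or more of the other scalings. In the epithelial list the median was 0.014 and the mean -0.0093, and the ribosomal median of -0.0037 lay against an upward camera direction. Limma also called 0 of the acinar, leukocyte, endothelial, stromal, red cell and hepatocyte markers between the times, with 0 at an unadjusted p under 0.05. Their medians were -0.10, -0.25, 0.10, -0.083 and -0.081 in the order acinar, leukocyte, endothelial, stromal, and red cell with hepatocyte.

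Most genes changed at 6 h had changed the same way at 72 h. Of the 46 genes that rose at 6 h, 44 also rose at 72 h. Of the 14 that fell, 12 also fell, and 0 genes were called in opposite directions by limma. The exceptions among the named genes were UGCG and TARDBP, which stood at -0.087 and -0.068 at 72 h, and SCD, where the brightest probe set stood at -0.069 while its 3 other probe sets were lower and passed (-1.02, -0.89 and -0.87). Across genes, which are not independent replicates, the log2 changes at 6 h and 72 h had a Pearson correlation of 0.373. Simulated unchanged groups that shared 3 simulated DMSO arrays gave 0.286 (0.255 to 0.317, 100 simulated draws). With single arrays left out in turn, the lowest observed correlation lay inside this simulated range. How far 0.373 lies beyond chance is therefore uncertain. The covariance of the log2 changes was 0.0106 against 0.00359 simulated, a difference of 0.00696. The changes had the same sign in 59.6% of genes, against 59.3% simulated. Independent calls would give 3.83 shared rises and 2.56 shared falls. Both comparisons use the same DMSO arrays, which those values ignore, and no value that allows for this was worked out for the overlap of calls.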

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

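Cyclic loess normalization was tried only after the data had been seen. Of 128 named genes, 104 differed between the 6 h and the 72 h arrays, by a limma test of the difference itself (44 higher and 60 lower at 72 h). Values are log2 differences of the 72 h from the 6 h arrays, where the shared DMSO arrays cancel and time in culture is not separated from exposure. Most of these genes were named because of a large 72 h change, so the number is no measure of how many genes differ. Higher at 72 h were KISS1R (1.45), RAB26 (1.45), CCM2L (1.34), IFITM1 (1.21), TM7SF2 (1.18), CEBPA (1.05), ASNS (1.001) and PCK2 (0.99). Next came ADCY9 (0.97), SLC7A11 (0.93), FRAT1 (0.89), PTCH1 (0.80), H1-2 (0.71), SREBF1 (0.68), H2AC6 (0.67) and H2BC4 (0.67). Positive differences were also found for HOXC4 (0.57), CYP1B1 (0.52), PAX2 (0.51), JUP (0.45), MUC1 (0.45), OCLN (0.45), DDIT4 (0.43) and TRIB3 (0.42). Further genes on this side were CHAC1 (0.40), GDF15 (0.40), PIR (0.36), SESN2 (0.36), NRARP (0.35), KIF11 (0.35), CLDN7 (0.34) and TXNRD1 (0.33). To these are added TOP2A (0.33), NQO1 (0.32), MAP1LC3B (0.27), NDUFB3 (0.26), EDN1 (0.26), HOXC6 (0.23), LSS (0.21) and HOXC10 (0.20). The smallest positive differences were those of HOXB6 (0.19), TARDBP (0.19), UGCG (0.18) and VEGFA (0.17).

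Lower at 72 h were PODXL (-2.67), TFPI2 (-2.40), GAL (-2.19), MATN2 (-1.90), TGM2 (-1.88), IFIT3 (-1.78), CLMP (-1.78), SGK1 (-1.74) and FAXC (-1.56). They were followed by ADAM19 (-1.48), COL6A1 (-1.45), IFIT2 (-1.36), CA2 (-1.01), KRT7 (-1.004), OASL (-0.96), ENO2 (-0.96), MANF (-0.91) and LOX (-0.89). Negative differences of middle size belonged to CXCL8 (-0.89), PLK3 (-0.87), COL5A1 (-0.87), HES1 (-0.82), CTSL (-0.81), CLDN4 (-0.76), PTPRN2 (-0.73), PDK1 (-0.67) and F3 (-0.67). In the same direction lay HSD17B7 (-0.66), SPRY4 (-0.64), CXCL1 (-0.62), JAG1 (-0.60), S100A4 (-0.59), CDC45 (-0.56), LIF (-0.54), GINS2 (-0.53) and CTSB (-0.52). Then followed CDC6 (-0.52), KRT8 (-0.52), DUSP5 (-0.50), PMEPA1 (-0.50), DNAJB1 (-0.46), CCN2 (-0.44), DNAJB11 (-0.43), PFKFB3 (-0.39) and CDKN1A (-0.38). Differences nearer to 0 were those of HDAC4 (-0.37), CCNE1 (-0.37), HSPB1 (-0.37), DDIT3 (-0.34), CCL2 (-0.34), UBE2C (-0.31), MT1X (-0.30), SCD (-0.28) and HOXB2 (-0.27). The smallest negative differences belonged to HPRT1 (-0.27), AURKB (-0.26), GUSB (-0.26), MT1G (-0.25), JUN (-0.23) and MSMO1 (-0.16).

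Among genes changed at 72 h against DMSO more fell than rose, with falls making up 68.7% of the calls on the values as deposited. Falls made up 54.3% after quantile normalization and 52.5% after cyclic loess, so the imbalance depends on how values are scaled between arrays. The median log2 change over all genes was 0.0017 and 0.0086 after these, against -0.062 as deposited. Both bring that median near 0, so the more even split cannot show where the imbalance came from. Without 72 h replicate 2, the array with the lowest correlation to the others, falls still made up 64.6%, which argues against that array as the whole cause. The median over all genes was then -0.022, so part of the downward shift went with that array. Without 72 h replicates 1 and 3 the median was -0.095 and -0.064. Replicate 3, which also had a low upper quartile (99.7), stayed in the fit without replicate 2. What stays open is whether all or part of the imbalance is a real loss of transcripts at 72 h. Quantile and loess scaling would remove one, and no biological explanation was tested.

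PDX1, which set the dose of the study, was not detectably higher on the arrays at either time. A signal too near the low end to move could account for this. Of 1651 genes within 0.5 log2 units of its mean, 10 rose at 72 h (0.606%) and 47 fell, while 9.49% of the brighter genes rose. The smallest rise near the PDX1 signal was 1.34-fold. Genes of this signal therefore rose at times, but rarely, and the test leaves the explanation open. Whether the labels' induction refers to another measurement of PDX1 was not tested here.

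The counts of changed genes were set against other ways to divide the same 6 arrays into 3 and 3. There are 10 in each comparison, the real one included, so that a share under 0.05 cannot be reached. The real division gave 60 genes at 6 h, 3378 at 72 h and 3037 between the times. The highest of the other divisions gave 0 in each by limma, so 1 of 10 divisions, the real one, reached the count each time. Each other division mixes arrays of both groups, so any real difference between the groups enters the spread and lowers the count. The counts of 0 therefore do not measure what chance gives, and no conclusion is drawn from them.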

How the results depend on the processing

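Cyclic loess normalization and array weights were chosen after seeing the data. Over the alternatives, 144 of 174 values of the main results, 952 of 1044 of the lists and 6654 of 7095 of the named genes kept their call, or a count within 1.5 times. For lists and named genes, a change of sign was counted only where at least 1 of the 2 fits called the value. Values called in neither fit could change sign and still count as kept. Of the rest, 80 list and 370 gene values lost a call, 12 and 66 gained one and 5 gene values changed sign by that rule. Of the main results, 27 values moved by more than that and 3, those of PDX1 at 72 h, changed sign. The number of genes changed at 6 h against DMSO, 60, became 37 with median centring, 23 with averaged probe sets, 30 without _s_at and _x_at probe sets, 23 without the trend and 211 with array weights. Leaving out 1 array gave 28 to 44: 31, 38 and 34 without DMSO replicates 1, 2 and 3, and 28 and 34 without 6 h replicates 2 and 3. Limma called 0 genes past 2-fold at 6 h with averaged probe sets and with the pseudocount, and 0 to 1 with 1 array left out (0 without DMSO replicate 1 or 6 h replicate 2). For genes changed at 72 h against DMSO the count became 2086 with median centring and 5399 with every probe set tested, and for genes changed at least 2-fold, 72 h against DMSO, 61 with averaged and 178 with all probe sets. For genes different between 72 h and 6 h the counts were 1782 and 4759, and for genes changed at least 2-fold, 72 h against 6 h, 41 and 122; testing every probe set tests a larger number of features. PDX1 at 72 h became -0.0082 with averaged probe sets and ran from -0.14 to 0.24 with 1 array left out, below 0 without DMSO replicate 2 (-0.0099) and without 72 h replicate 3. The correlation of 6 h and 72 h effects was 0.410 with a stricter filter and 0.312 to 0.431 with 1 array left out. Averaged probe sets turned FOXA2 at 72 h to -0.013 and, between the times, EDN1 to -0.029 and VEGFA to -0.046. Without _s_at and _x_at probe sets TOP2A at 72 h became -0.040 and GINS2 between the times 0.040. Apart from the larger number of probe sets and the smaller number of arrays, the cause was not tested. Same-numbered arrays deviated together with correlations from -0.259 to 0.202, above 0.1 in 4 of 9 pairs, so the numbers were not taken as pairing. With the replicate block 54, 3193 and 2840 genes were called, 52, 3126 and 2763 of them shared with the unblocked fit. Signal over background limits what was seen: genes under a linear signal of 17.8 are not in the gene counts and lists unless the filter was dropped.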

Other observations

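The lists of HOX genes, other homeobox genes, aminoacyl-tRNA synthetases and BMP and ID family genes were chosen after changes of single members had been seen. Their list p values were adjusted over these added lists alone, the HOX B and C clusters among them, and not together with the lists fixed beforehand. HOX genes, which set position along the body axis, shifted upwards as a group at both times. Of 19 measured, 7 rose and 12 did not pass at 6 h, with a median log2 change of 0.25 (camera adjusted p = 8.8e-29, and adjusted p = 0.000667 with an estimated correlation). HOXC9 rose 1.74-fold, HOXB8 1.62-fold, HOXC6 1.52-fold and HOXB6 1.49-fold (SE 0.091, 0.072, 0.038 and 0.065 log2 units, n = 3 arrays per group). HOXC10, HOXB3 and HOXB5 rose 1.43-fold, 1.32-fold and 1.28-fold. At 72 h 12 rose, among them HOXC9 (2.08-fold) and HOXC4 (2.04-fold), HOXB2 fell by 0.20 on the log2 scale and 6 did not pass (adjusted p = 0.00598 with an estimated correlation). With median centring HOXB2 no longer passed at 72 h. The C cluster had a median of 0.38 at 6 h and 0.58 at 72 h over 8 genes, and the B cluster 0.25 and 0.33 over 9. The 48 other homeobox genes shifted slightly upwards at 6 h by camera with its preset correlation (median 0.044, adjusted p = 0.0493), but not with an estimated one (adjusted p = 0.396). PAX2 rose and DLX2 fell at 6 h. At 72 h their median was -0.076, and the camera adjusted p of 0.626 became adjusted p = 0.828 with an estimated correlation. That median, against an upward camera direction, changed sign after quantile and cyclic loess normalization.

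Technical sources of the HOX rise at 6 h were tested. Signal shared between HOX paralogs would spare the plain probe sets, those without a suffix for shared probes, and their median was 0.23, with 12 of 13 above 0. A single array would leave the others near 0, and the lowest of the 3 arrays stood at 0.28, against -0.043 to 0.046 for DMSO arrays set against each other. A shift shared by genes of like signal was tested with 10000 random lists, all of which lay below the HOX median (100% below, the highest at 0.092). These values argue against the 3 technical explanations, and a HOX response to BRD7552 is a candidate explanation, found and tested on the same arrays.

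Since ATF4 targets rose at 72 h, a wider amino acid response that takes in the cytosolic aminoacyl-tRNA synthetases was put forward as a hypothesis. Of 17 measured synthetases, 10 rose, 1 fell and 6 did not pass at 72 h. Their median log2 change was 0.28, with adjusted p = 0.00598 with an estimated correlation. At 6 h limma called 0, with 6 at an unadjusted p under 0.05, a median of 0.031 and adjusted p = 0.0450 with an estimated correlation. The median at 72 h lay between 0.28 and 0.32 under the other scalings. The values go with this hypothesis, but it was put forward and tested on the same arrays, so they are no independent support. It does not say what raised these genes.

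The BMP and ID family list, prompted by ID1, ID2 and ID3, had 12 measured members, of which these 3 fell at 6 h. The 7 members outside the fixed TGF-beta and YAP list had a median log2 change of -0.084, and limma called 0 of them, with 1 at an unadjusted p under 0.05. At 72 h 6 members fell and 6 did not pass (adjusted p = 0.160 with an estimated correlation).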
